A study of Homo sapiens with 4 samples.

How the data were processed

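Total RNA from 2 human prostate cancer cell lines was sequenced after removal of ribosomal RNA, in 2 libraries per line, on an Illumina HiSeq 2000. LNCaP is a line from a lymph node metastasis that depends on androgen and is labelled as primary cancer, and C4-2 is a subline of LNCaP labelled as castration-resistant. Per the labels' protocols, both lines were kept in RPMI medium with serum stripped of steroids. Nothing in the labels tells whether the libraries of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical.

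Samples were placed in groups by their titles. The deposited data of each sample carry the name of the other cell line, so that the samples titled LNCaP are stored under the name C4-2 and the reverse. Groups follow the titles and the cell line labels, and the text speaks of the libraries labelled LNCaP and C4-2. If the stored names were right, every direction given here would turn round.

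Per the submitters' processing notes, reads were aligned with TopHat2 2.0.6 and Bowtie to hg19 (GRCh37). The authors deposited, per the file headers, a tag count and an RPKM value for each strand of 41351 entries of RefSeq transcripts. The tool that counted the tags and the version of the transcript models are not given in the sources used here. Isoforms with the same span had different counts, so the counts were taken to cover exons, and the deposited RPKM values were found to divide by exon length and by a single total per library. That total, recovered from transcripts of a single exon, was 189.87 and 197.63 M tags (M, mega) in the libraries labelled LNCaP and 241.07 and 171.51 M in those labelled C4-2. The library kit named in the labels is not stated to keep the strand, yet between 1.18% and 1.80% of the tags lay on the strand opposite to the transcript, and the sense column was used.

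Transcripts were named through a RefSeq table of assembly GRCh38.p14, used for names only, which gave a symbol to 38974 of 40304 distinct accessions. Transcripts without a symbol held 2.06% to 2.15% of the sense tags and stayed out of library sizes and tests. For each of the 22985 symbols the transcript with the highest mean share of tags over the 4 libraries was kept, because isoforms count the same tags again. Coordinates are those of the deposited data (hg19), counted from 1. The sense tags of these transcripts came to 58.9 and 70.4 M in the libraries labelled LNCaP and 163.2 and 119.1 M in those labelled C4-2. Intervals given for low counts cover counting error only, at a level of 95%, and a group with 0 tags was set to a floor of 3 tags over the group.

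Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after its filter on low counts and TMM normalization, with the cell line as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are C4-2 over LNCaP as labelled, standard errors were derived from the fold change and its F statistic, and levels are TMM-scaled CPM (counts per 1e6 tags). On counts simulated from these libraries with 15787 genes tested, the test found 34% of 50 genes changed 1.25-fold, 84% of 50 changed 1.5-fold, 96% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 15 false calls. All other simulated genes were unchanged, whereas 79.9% of tested genes were called in the data. These rates thus do not carry over to the data. Counts of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 25.6 for LNCaP and 13.6 for C4-2, so no library was taken for a copy of another.

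Gene lists (30) were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the first group of other settings given here. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 29 lists with members tested, and again with a correlation estimated from the data. Simulated sets of 30 genes raised 1.5-fold were found in 20 of 20 cases with the preset and in 17 of 20 with the estimated correlation, and 0 of 100 unchanged sets were called with either. The simulated genes were drawn independently, against a background that mostly did not change. In the data 79.9% of tested genes were called and estimated correlations reached 0.61 (histone genes), so those rates do not carry over to the data. Mitochondrially encoded mRNAs, a list of 13, and the 7SK RNA were not analysed here.

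The genes named were the 10 highest and 10 lowest fold changes among called genes with a log2 average CPM of at least 2 and a symbol that is not only a clone or LOC name, up to 4 members of each list by smallest adjusted p (or, where fewer than 2 were called, by average level), and KLK3, KLK2, TMPRSS2, FKBP5, CDK9, CCNT1 and HEXIM1. Some genes that meet the rule are not reported here. Genes outside that rule are said to have been chosen after their values were seen.

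Other settings chosen beforehand were the size factors of DESeq2 1.42.0 within edgeR, total counts, no filter and a stricter filter (at least 1 CPM in 2 libraries and 50 tags in total), the DESeq2 Wald test, limma-voom, leaving out abundant non-coding RNAs, the replicate number as a block, leaving out each library, and the estimated correlation in camera. Chosen after seeing the data were the longest transcript per gene, the sum of transcripts per gene, removal of smooth trends with GC content and exon length (splines with 4 degrees of freedom), and scaling to the library totals behind RPKM. GC content came from the longest GENCODE transcript of the same symbol (models lifted to GRCh37), exon length came from the deposited counts and RPKM values, and GC content was known for 98.3% of the tested genes. Tables were handled with Python 3.11.15 and pandas 2.3.3.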

Results

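The series holds total RNA sequencing of LNCaP and C4-2 prostate cancer cells grown without steroids, with 2 libraries per line, and its title concerns activation of the elongation kinase P-TEFb by enhancer RNAs of lethal prostate cancer. C4-2 was derived from LNCaP by growth in castrated mice, so the comparison asks how gene expression differs between a castration-resistant subline and its parent. Sense tags in exons of named genes numbered 58915517 and 70447246 in the libraries labelled LNCaP and 163168252 and 119073455 in those labelled C4-2. They made up 31.03% and 35.65% of the library total behind the deposited RPKM values in the libraries labelled LNCaP, against 67.68% and 69.43% in those labelled C4-2. The names under which the data are stored contradict the sample titles, so that each direction below is that of the labels and would turn round if those names were right.

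**Figure D1:**
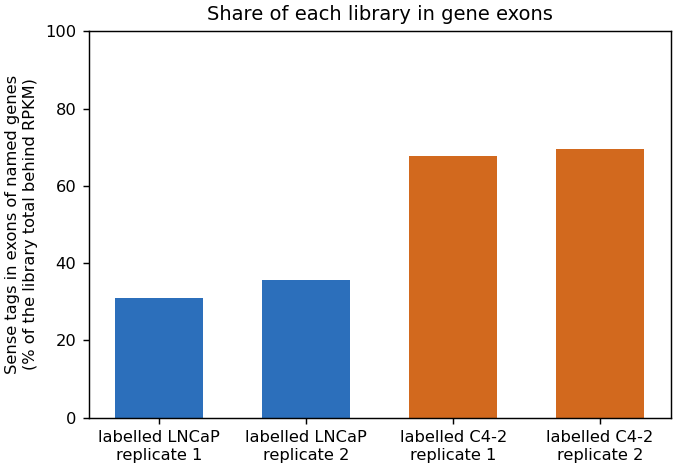
Bars give the sense tags in exons of named genes as a percentage of the library total behind RPKM, for each of the 4 libraries. Both libraries labelled C4-2 stand at 67.68% or above and both labelled LNCaP at 35.65% or below.

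Across the genome, the prostate-specific antigen gene KLK3 and its neighbour KLK2 were far lower in the libraries labelled C4-2, while the transmembrane protein gene TMEFF2 and the steroid receptor co-chaperone gene FKBP5 were higher. The nuclear RNAs MALAT1 and NEAT1, HOX genes and cancer-testis genes were lower there, and genes of cholesterol synthesis and glycolysis were higher, though none of these 4 list calls held with an estimated correlation (adjusted p = 0.49 for each). Of 15975 genes tested, 6433 were higher and 6339 lower in the libraries labelled C4-2 (edgeR quasi-likelihood test, adjusted p under 0.05), and 1868 were higher and 2890 lower by at least 2-fold. The values of the lines did not overlap for 89.9% of tested genes, where chance gives 33.3% for 2 libraries against 2. The biological coefficient of variation between replicates was 6.44%.

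These directions are relative to the typical gene. Scaling to the library totals behind RPKM raised the median log2 fold change by 1.004 and gave 11573 genes higher and 1753 lower, 86.8% of calls being higher against 50.4% in the main test. With that scaling the medians of the cell cycle, basal epithelial, immune and endothelial, antigen presentation, unfolded protein response, growth factor, lncRNA, chromatin, histone and ribosomal protein lists turned positive, as did CCNT1, EZH2, LAMA3, LYZ, RPS3A and VWF. The genes KMT2B, RPL17 and PECAM1 lost their calls.

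**Figure D2:**
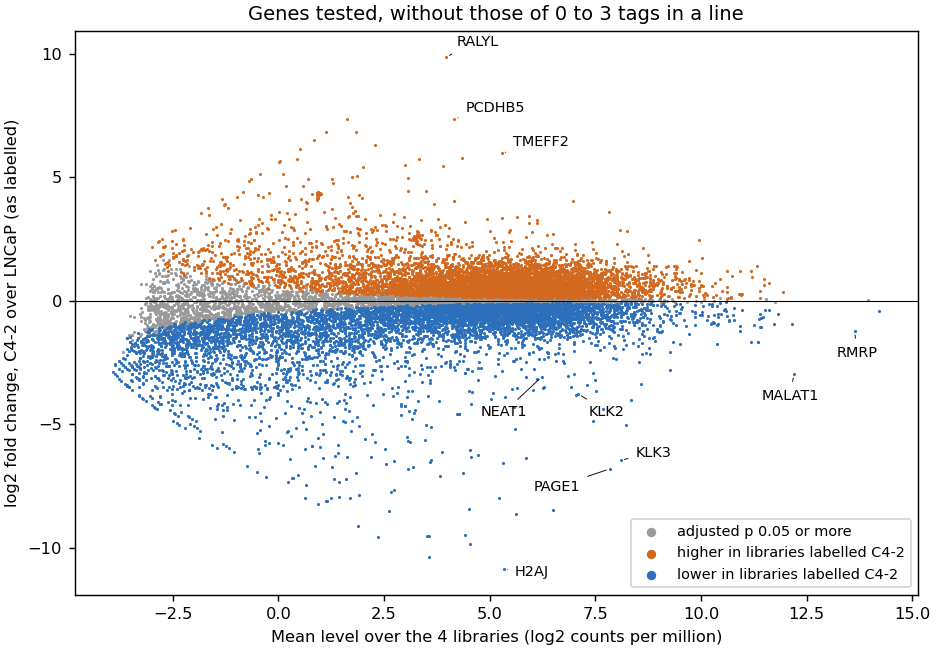
Each point is a tested gene, with its mean level over the 4 libraries in log2 CPM on the x axis and the log2 fold change of C4-2 over LNCaP, as labelled, on the y axis. Orange genes were higher and blue genes lower at an adjusted p under 0.05, grey genes did not pass, and the 239 genes with 0 to 3 tags in a line are left out. KLK3 lies at -6.46, TMEFF2 at 5.96 and MALAT1 at -2.99.

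Among the 10 genes with the highest fold changes was DNAJC15, which encodes a mitochondrial co-chaperone (hg19 chromosome 13, 43597362 to 43683306, plus strand). It had 0 tags in both libraries labelled LNCaP and 16.4 ± 0.54 CPM (SD, n = 2) in those labelled C4-2, at least 713-fold higher. RALYL, a gene for an RNA-binding protein on chromosome 8, reached 29.6 ± 0.56 CPM against 0.031 ± 0.0036, a log2 fold change of 9.86 ± 0.15 (SE). TMEFF2, a transmembrane protein gene of prostate and brain, was 62.4-fold higher, and the kinesin gene KIFC3, the opioid receptor gene OPRK1 and the calcium channel gene CACNA1H were 54.5-fold, 45.4-fold and 43.1-fold higher. The protocadherin genes PCDHB5 and PCDHB2 had log2 fold changes of 7.36 and 5.74, and the zinc finger gene ZNF648 had 6.29. Without LNCaP replicate 2, PCDHB5 stood at 8.18 and ZNF648 at 6.97. BHLHA9, the remaining gene, was at least 674-fold higher, but its tags numbered 3381 and 925 in the libraries labelled C4-2, with 3341 and 930 on the opposite strand, and its fitted fold fell 2.28 times without C4-2 replicate 1. With as many tags on either strand, it is uncertain that its tags stem from the mRNA, so that the bound is one on tags and not on expression.

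At the other end lay SLC22A3, an organic cation transporter gene (hg19 chromosome 6, 160769405 to 160873611, plus strand), with 91.8 ± 0.42 CPM in the libraries labelled LNCaP and a single tag over both libraries labelled C4-2, a ratio of 25576 (counting interval 4589 to 1010270). RGL3 had 0 tags in the latter and was at least 1305-fold lower. CTAG1A and CTAG1B, copies of the gene for the tumour antigen NY-ESO-1, had the same tags, so they count as a single signal that was at least 916-fold lower. GALC, which encodes a lysosomal galactosylceramidase, had 2 tags over both libraries labelled C4-2 against 1383 and 1630, a ratio of 3208 (counting interval 887 to 26503). ERVMER34-1, NNT-AS1, SLC25A43 and RGS2 also kept 1 or 2 tags, with ratios of 2344 (648 to 19364), 2624 (470 to 103710), 2587 (464 to 102280) and 1824 (504 to 15073). The fitted folds of these 5 genes and of SLC22A3 moved by 2.09 to 5.55 times without C4-2 replicate 1 and by 1.57 to 3.73 times without C4-2 replicate 2. H2AJ, a histone variant gene, fell from 82.9 ± 6.72 CPM in the libraries labelled LNCaP to 0.044 ± 0.0096.

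Androgen-induced genes split between the lines. KLK3 (hg19 chromosome 19, 51358171 to 51364020, plus strand) had 545 ± 17.1 CPM in the libraries labelled LNCaP and 6.18 ± 0.067 in those labelled C4-2, a log2 fold change of -6.46 ± 0.055 (SE, adjusted p = 6.51e-10), and overlaps another listed gene on its strand. KLK2 and the zinc-binding glycoprotein gene AZGP1 were also lower, at -3.78 ± 0.054 and -3.15 ± 0.049. Against these, TMEFF2, the steroid receptor co-chaperone gene FKBP5 and the serine protease gene TMPRSS2 were higher, at 5.96, 0.86 and 0.60. Of 44 members 22 were higher, 18 lower and 4 did not pass, with a median of 0.19 and an adjusted p of 0.66 for the list (camera, two-sided), or 0.71 with an estimated correlation. In the androgen-repressed list 6 of 11 members were higher and 3 lower (median 0.30, adjusted p = 0.29). There the opioid receptor gene OPRK1 and the glucuronosyltransferase gene UGT2B11 were higher (5.51 and 2.39) and the kinase inhibitor gene CAMK2N1 was lower (-3.61).

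**Figure D3:**
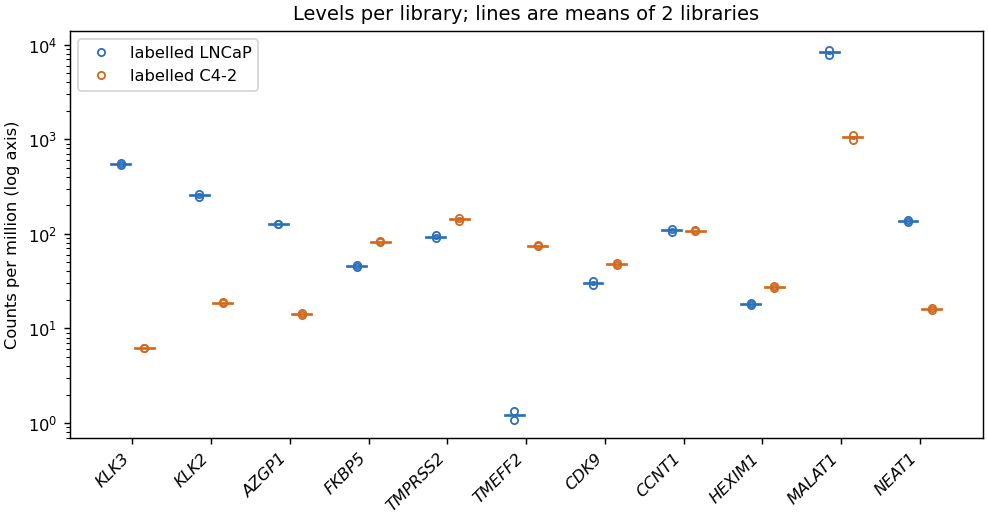
Open circles give the CPM of each library on a log axis and horizontal lines the mean of the 2 libraries of a line, blue for LNCaP and orange for C4-2 as labelled. KLK3, KLK2, AZGP1, MALAT1 and NEAT1 lie lower and FKBP5, TMPRSS2 and TMEFF2 higher in the libraries labelled C4-2, while CCNT1 overlaps (109 against 108 on average).

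The title's subject, P-TEFb, pairs the kinase CDK9 with cyclin T and is held inactive by HEXIM proteins on the 7SK RNA. CDK9 had 47.6 ± 1.80 CPM in the libraries labelled C4-2 and 30.1 ± 1.94 in those labelled LNCaP (log2 fold change 0.66 ± 0.063, adjusted p = 2.44e-05), and HEXIM1 had 27.3 ± 0.57 against 18.0 ± 0.70 (0.60 ± 0.057). On the strand opposite to HEXIM1 lay 584 and 397 tags in the libraries labelled C4-2 (sense 4458 and 3178). In those labelled LNCaP there were 564 and 630 (sense 1052 and 1310). CCNT1, the gene for cyclin T1, had 108 ± 0.70 against 109 ± 5.41 CPM and did not pass the test (-0.016 ± 0.045, adjusted p = 0.76). NELFB, a subunit of the negative elongation factor, and the elongation factor genes SUPT16H and SUPT6H were higher (1.30, 1.18 and 0.91), and MLLT3, a gene of the super elongation complex, was lower (-1.44). Of 34 members 20 were higher, 9 lower and 5 did not pass, with a median of 0.30. The list as a whole did not pass (adjusted p = 0.14, and 0.49 with an estimated correlation).

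**Figure D4:**
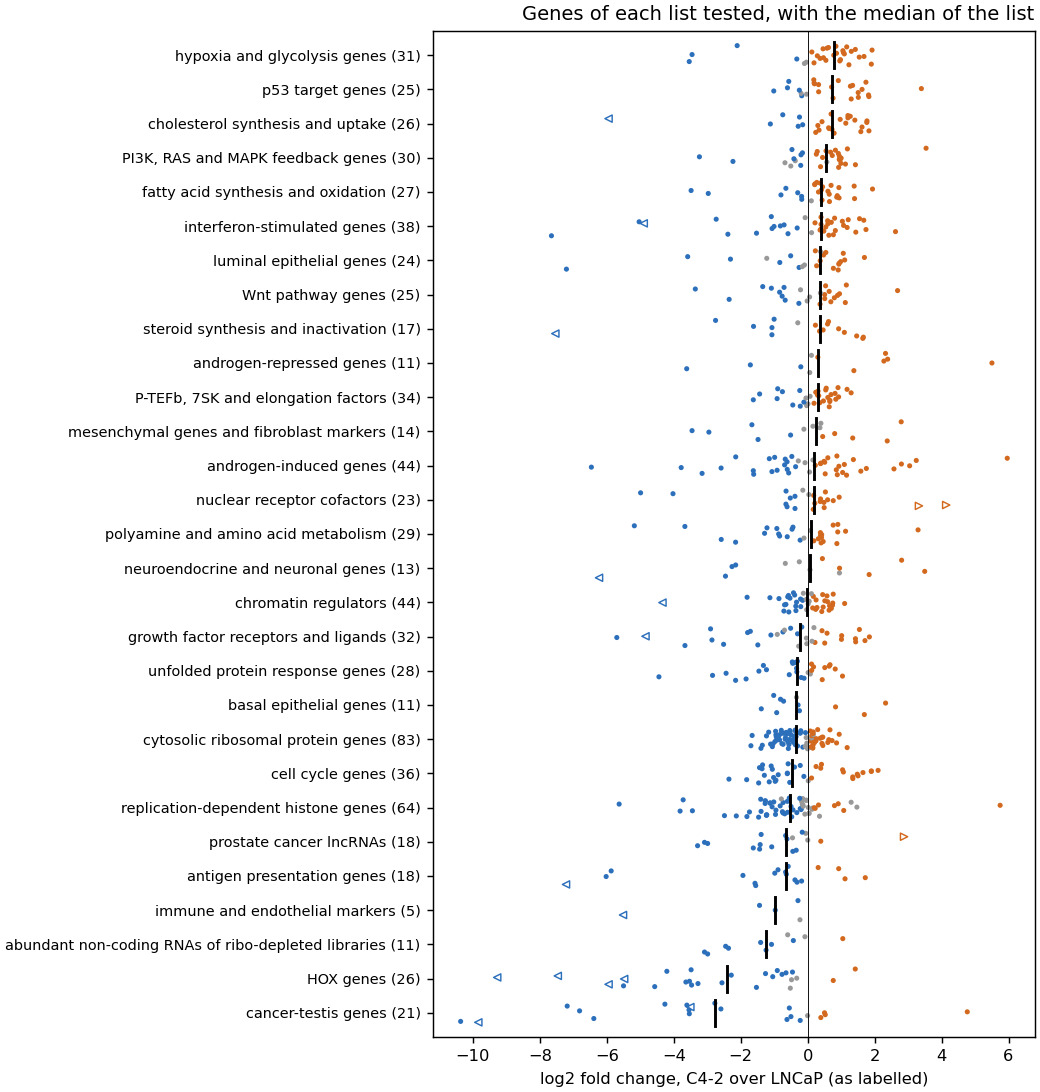
Each point is a tested gene of a list, with its log2 fold change of C4-2 over LNCaP as labelled on the x axis, orange if called higher, blue if called lower and grey if not called. Black lines are list medians, numbers in brackets count the genes, and open triangles mark genes with 0 to 3 tags in a line, drawn at their bound or tag ratio. Medians run from -2.77 for cancer-testis genes to 0.78 for hypoxia and glycolysis genes, and with library totals the medians of 10 lists that are negative here turn positive.

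Lists that were higher in the libraries labelled C4-2 concerned metabolism and stress. In cholesterol synthesis and uptake 20 of 26 members were higher and 6 lower (median 0.71, camera adjusted p = 0.0064), with DHCR7 at 1.83, HMGCS1 at 1.62 and SQLE at 1.27, all genes of the sterol pathway. Hypoxia and glycolysis genes were higher for 25 of 31 members and lower for 4 (median 0.78, adjusted p = 0.0020): the hexokinase genes HK2 and HK1 stood at 1.68 and 1.54 and the aldolase gene ALDOC at 1.90. The angiogenic factor gene VEGFA was lower at -2.11. For p53 targets 18 of 25 were higher and 5 lower (0.72, adjusted p = 0.036), among them the kinase gene PLK2 at 3.40, the cell cycle inhibitor gene CDKN1A at 1.82, BTG2 at 1.83 and SESN1 at 1.28. In fatty acid synthesis and oxidation 19 of 27 were higher and 7 lower (0.41, adjusted p = 0.041). The citrate lyase gene ACLY, the elongase gene ELOVL6 and the desaturase gene FADS1 were higher (1.40, 1.94 and 0.93), and the racemase gene AMACR, a prostate cancer marker, was lower (-2.97). None of these 4 lists passed with an estimated correlation (adjusted p = 0.49 for each), and with library totals only the p53 list did. The p53 list also lost its call with the stricter filter (adjusted p = 0.076, from 0.014 to 0.49 over its alternatives). The fatty acid list lost its call with the stricter filter, without abundant non-coding RNAs, with the replicate block and after GC and length correction (from 0.015 to 0.49). After that correction its median was 0.46 (quartiles -0.22 and 0.70, before -0.034 and 0.78).

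Developmental and germline genes were lower in the libraries labelled C4-2. Of 26 HOX genes, which pattern the body axis, 21 were lower and 2 higher (median -2.42, camera adjusted p = 0.00032), with HOXA11 at -4.57, HOXA5 at -3.28 and HOXA10 at -1.53. HOXB7 had 0 tags in both libraries labelled C4-2 and was at least 620-fold lower. Cancer-testis genes, normally silent outside the germline, were lower for 16 of 21 members and higher for 4 (-2.77, adjusted p = 0.0064): PAGE1 had 455 ± 23.3 CPM in the libraries labelled LNCaP and 4.03 ± 0.47 in those labelled C4-2, and MAGEA1 and CTAG2 stood at -6.39 and -10.37. XAGE1B, at -4.27, shares its tags with a copy and is uncertain. With an estimated correlation the adjusted p of both lists was 0.49.

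Non-coding RNAs, histone genes and ribosomal protein genes were lower as well, in libraries whose exon share was higher (67.68% and 69.43% against 31.03% and 35.65%). MALAT1 fell from 8331 ± 693 CPM in the libraries labelled LNCaP to 1050 ± 81.7 in those labelled C4-2, and NEAT1 stood at -3.08, GAS5 and SNHG1, which overlap the small nucleolar RNAs they host, at -1.44 and -1.39, and the RNAs RNU12 and RMRP at -2.45 and -1.24. The list of prostate cancer lncRNAs had 13 of 18 members lower and 2 higher (median -0.64, adjusted p = 0.019), and that of abundant non-coding RNAs 8 of 11 lower and 1 higher (-1.24, adjusted p = 0.021). Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were lower for 39 of 64 and higher for 7 (-0.52, adjusted p = 0.0063), with H3C11 at -5.63, H4C16 at -3.72, H1-5 at -1.82 and H1-2 at -1.47. Cytosolic ribosomal protein genes were lower for 48 of 83 and higher for 27 (-0.35, adjusted p = 0.049), with RPL21 at -1.70, RPS15A at -1.66, RPL17 at -1.06 and RPS3A at -0.96, of which RPL21, RPL17 and RPS3A overlap other genes on their strand. After GC and length correction the lncRNA, histone and ribosomal protein lists did not pass (adjusted p = 0.15, 0.24 and 0.86). The lncRNA median stood at -0.51 (quartiles -0.95 and 0.040, before -1.43 and -0.21), the histone median at -0.24 (quartiles -0.97 and 0.33, before -1.22 and -0.037) and the ribosomal protein median at 0.016. For the abundant RNAs that check is void, since GC content was known for 63.6% of members. With an estimated correlation the adjusted p of the lncRNA, abundant RNA, histone and ribosomal protein lists was 0.49, 0.49, 0.71 and 0.76. Without the abundant non-coding RNAs, of which MALAT1 and NEAT1 are also in the lncRNA list, the lncRNA and ribosomal protein lists lost their calls (adjusted p = 0.052 for both, the lncRNA list ranging from 0.0028 to 0.49 over its alternatives). The ribosomal protein call also ended without LNCaP replicate 2, C4-2 replicate 1 or C4-2 replicate 2 (adjusted p = 0.10, 0.086 and 0.095), with the replicate block (0.079), without a filter (0.062) and with the sum of transcripts (0.052). Its adjusted p ranged from 0.011 to 0.86 over its alternatives.

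The remaining lists did not pass as a whole, though single members differed widely. Cell cycle genes were higher for 14 and lower for 21 of 36 (median -0.46, adjusted p = 0.40): the replication licensing genes MCM6 and MCM4 were higher (2.10 and 1.90) and the mitotic cyclin genes CCNB2 and CCNB1 lower (-2.35 and -1.82). In the unfolded protein response 9 of 28 were higher and 17 lower (median -0.31, adjusted p = 0.17), with the stress factor gene ATF4 at -1.84, asparagine synthetase ASNS at -2.15, DNAJB9 at -2.44 and CHAC1 at -4.44. Polyamine and amino acid genes were higher for 14 and lower for 13 of 29 (adjusted p = 0.97), but the amino acid transporter genes SLC7A5 and SLC7A11 were lower (-5.18 and -3.67), as was CTH (-2.58). Antigen presentation genes were lower for 14 and higher for 4 of 18 (median -0.65, adjusted p = 0.055, or 0.042 and 0.044 without C4-2 replicate 1 and 2 and 0.045 without a filter, from 0.042 to 0.49 over its alternatives), with B2M at -1.55 and the immunoproteasome gene PSMB8 at -5.87. The peptide transporter gene TAP1 was higher (0.93). HLA-DRA stood at -6.02, or at -5.33 without C4-2 replicate 1 and -6.88 without C4-2 replicate 2. Interferon-stimulated genes were higher for 23 and lower for 13 of 38 (median 0.40, adjusted p = 0.29), with PARP9 higher (1.04) and BST2 and PARP14 lower (-7.66 and -5.04).

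Markers of lineage were mixed. Luminal genes were higher for 14 and lower for 6 of 24 (median 0.38, adjusted p = 0.25), with the keratin genes KRT8 and KRT18 and the cadherin gene CDH1 higher (1.70, 1.11 and 0.91). CDH3, placed in this list beforehand though it is not specific to luminal cells, was lower (-7.21). Basal genes were higher for 3 and lower for 7 of 11 (median -0.33, adjusted p = 0.55), with ITGA6 and BCL2 higher (0.83 and 1.69) and ITGA2 and LAMA3 lower (-1.39 and -0.72). Neuroendocrine and neuronal genes were higher for 5 and lower for 4 of 13 (median 0.069, adjusted p = 0.87), the tubulin gene TUBB3, NEFL and ENO2 being higher (2.81, 3.50 and 1.84) and DDC lower (-2.46). Mesenchymal and fibroblast genes were higher for 5 and lower for 5 of 14 (median 0.26, adjusted p = 0.97), with the intermediate filament gene VIM and COL6A2 higher (2.79 and 0.81) and the fibronectin gene FN1 and LOX lower (-2.95 and -3.45). Only 5 of 22 immune and endothelial markers had enough tags for the test, 4 of them lower (median -0.97, adjusted p = 0.14, or 0.042 without LNCaP replicate 2, from 0.042 to 0.49 over its alternatives), and none of the named ones exceeded 5 CPM: VWF had 4.19 ± 0.084 CPM in the libraries labelled LNCaP, LYZ 1.64 ± 0.0064, ITGAM 0.33 ± 0.071 (a tag ratio of 45.8, counting interval 11.9 to 390.2) and PECAM1 0.22 ± 0.13. ITGAM stood at -7.78 without C4-2 replicate 1 and at -4.59 without C4-2 replicate 2. LYZ had more tags on the opposite strand than sense tags, 127 and 146 in the libraries labelled LNCaP and 284 and 203 in those labelled C4-2. The call of PECAM1 (-1.44) ended without LNCaP replicate 1, C4-2 replicate 1 or C4-2 replicate 2, where it stood at -0.68, -1.48 and -1.40. That of VWF (-0.29) ended without the same libraries (-0.26, -0.33 and -0.24). Both calls also ended without a filter, by DESeq2 and with the sum of transcripts. So did that of VWF with the replicate block and that of PECAM1 with library totals.

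Signalling and regulator lists did not pass either. Growth factor genes were higher for 11 and lower for 14 of 32 (median -0.22, adjusted p = 0.57), with the receptor gene IGF1R higher (1.84) and its ligand gene IGF1, BMP7 and EGF lower (-5.70, -3.67 and -2.51). Wnt pathway genes were higher for 12 and lower for 9 of 25 (median 0.37, adjusted p = 0.63), with CCND1, MYC and CTNNB1 higher (1.12, 0.89 and 0.69) and the receptor gene FZD4 lower (-2.35). In the PI3K, RAS and MAPK feedback list 19 of 30 were higher and 7 lower (median 0.56, adjusted p = 0.091, or 0.045 without LNCaP replicate 2 and 0.034 without a filter, from 0.034 to 0.49 over its alternatives), with DUSP2 and IER2 higher (1.43 and 0.94), JUN 2-fold higher and PHLDA1 lower (-3.23). Nuclear receptor cofactors were higher for 13 and lower for 8 of 23 (median 0.18, adjusted p = 0.57), with NCOA2 and KDM1A higher (0.94 and 0.60) and the progesterone receptor gene PGR and EZH2 lower (-4.99 and -0.65). Steroid synthesis genes were higher for 10 and lower for 6 of 17 (median 0.36, adjusted p = 0.57), with HSD17B4, SRD5A3 and HSD17B10 higher (0.93, 0.59 and 0.46) and CYP1B1 at 0 tags in both libraries labelled C4-2, at least 186-fold lower. Chromatin regulators were higher for 19 and lower for 19 of 44 (median -0.0078, adjusted p = 0.97), with HDAC2 higher (1.10) and KMT2C and KMT2B lower (-1.81 and -1.13).

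Adjusted over the list alone, the counts of higher and lower members were the same as over all genes except for nuclear receptor cofactors (13 and 9), luminal genes (14 and 7), growth factor genes (11 and 15), feedback genes (19 and 8) and ribosomal protein genes (28 and 48). Median and mean differed in sign for steroid, neuroendocrine, luminal, mesenchymal, interferon, Wnt and polyamine genes, and for polyamine genes the median (0.085) also differed in sign from the camera direction, which was down. With an estimated correlation 0 lists passed camera, 1 having an unadjusted p under 0.05 (HOX genes, 0.039). That correlation lay below the preset 0.01 for HOX (-0.033), fatty acid (-0.017), lncRNA (-0.012) and abundant RNA genes (-0.043). A larger correlation between genes is thus not what ended these calls. For HOX genes the unadjusted camera p rose from 1.1e-05 to 0.039 all the same. For cholesterol genes the estimate (0.0106) was close to the preset, yet the unadjusted camera p rose from 0.00088 to 0.081. A call lost with the estimated correlation is thus not by itself a sign of correlated genes. The estimate lay further above the preset for hypoxia (0.059), p53 (0.068), cancer-testis (0.11), ribosomal protein (0.39) and histone genes (0.61).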

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

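The strand opposite to the transcripts was not part of any comparison set beforehand, and the measures in this part were chosen after the data were examined. Of 13418 genes with no other listed gene on the opposite strand, 311 had antisense tags above 0.5 of their sense tags, with at least 50 antisense tags in both libraries of a line. This held for 211 genes in the libraries labelled LNCaP, for 246 in those labelled C4-2, whose greater depth makes 50 tags easier to reach, and for 146 in both. As a share of the tags of these 13418 genes, antisense tags made up 1.07% and 1.17% in the libraries labelled LNCaP and 0.576% and 0.655% in those labelled C4-2. NRSN1 on chromosome 6 had 238375 antisense and 67 sense tags in the libraries labelled LNCaP, and 154373 and 29 in those labelled C4-2.

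In a few genes, chosen after their values were seen, antisense tags were many in single libraries or in those of a line. BHLHA9 had 3381 sense and 3341 antisense tags in C4-2 replicate 1 and 925 and 930 in C4-2 replicate 2, and 0 of either in the libraries labelled LNCaP. ZFAND2B had 2726 and 2667, and 1753 and 2043, in the same libraries, against 1504 and 68 over both libraries labelled LNCaP. LRRC8E had 567 and 522, and 736 and 644, in the libraries labelled LNCaP, against 5436 and 965 over those labelled C4-2. Elsewhere the antisense tags came from 1 library and outnumbered its sense tags. C4-2 replicate 2 had 19325 antisense and 8023 sense tags of B3GALT6 (433 and 11023 in C4-2 replicate 1), and 25476 and 10900 of KRTCAP2 (8 and 10200). C4-2 replicate 1 had 13293 and 7560 of SRGAP2 (24 and 5399 in C4-2 replicate 2), and LNCaP replicate 1 had 36064 and 14247 of GSR (36 and 16243 in LNCaP replicate 2).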

How the results depend on the processing

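The alternatives of transcript choice, GC and length correction and library totals were chosen after the data were examined, and the others before. The counts of 6433 genes higher and 6339 lower stayed within 1.5 times under every alternative but library totals, which gave 11573 and 1753 (genes differing at least 2-fold, higher in C4-2, numbered 7909, and genes differing at least 2-fold, lower in C4-2, 1139), 7 androgen-induced and 2 elongation genes lower, 1 other list higher by camera and 2 chromosomes called; its own construction adds the median shift of 1.004. With those totals, medians turned to 0.54 for cell cycle, 0.67 for basal, 0.035 for immune and endothelial, 0.35 for antigen presentation, 0.69 for unfolded protein response, 0.78 for growth factor, 0.37 for lncRNA, 0.99903 for the list: chromatin regulators, 0.48 for histone and 0.66 for ribosomal protein lists, and CCNT1 to 0.99, EZH2 to 0.35, LAMA3 to 0.29, LYZ to 0.035, RPS3A to 0.047 and VWF to 0.71. GC and length correction turned the medians of neuroendocrine (-0.17), polyamine (-0.025) and ribosomal protein genes (0.016) and CCNT1 (0.0060), left 2 other lists lower by camera (for abundant non-coding RNAs, with GC known for 63.6%, the check is void) and 4 chromosomes called, and turned the direction of 132 called genes. With an estimated correlation 0 other lists were higher and 0 lower, against 4 and 6 with the preset. The stricter filter left 2 lists higher and turned the mesenchymal median to -0.20, and leaving out abundant non-coding RNAs left 3 lists lower: the removed list was lost, and the lncRNA and ribosomal protein lists lost their calls. Apart from library totals and fewer genes, the cause of these changes was not tested. CCNT1, which was never called apart from library totals, also turned to 0.027 without a filter and 0.0038 by DESeq2, and the chromatin median (-0.0078) turned to 0.034 without a filter.

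Leaving out each library in turn gave 5969 to 6573 genes higher and 5679 to 6188 lower (1818 to 1999 and 2718 to 2852 at least 2-fold), an androgen-induced median of 0.13 to 0.30 with 22 members higher and 16 to 17 lower, an elongation median of 0.28 to 0.33 with 20 to 21 higher and 7 to 9 lower, 4 to 5 other lists higher and 6 lower, and 5 to 7 chromosomes. CCNT1 ranged from -0.063 to 0.042, the median of the list: chromatin regulators from -0.0047 to 0.049 and the mesenchymal median from -0.20 to 0.31. A lone library is assumed to vary like those of the other line. Deviations of same-numbered libraries from the mean of their line had a correlation of -0.032 across genes, a single value with 2 libraries per line, which gives no ground to pair the samples by number; with the replicate block 12399 genes were called against 12772, and the androgen-induced median was 0.18. DESeq2 gives no list test here. Depth limits genes with 0 to 3 tags in a line, 239 of those tested.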

Other observations

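Chosen after the data were examined were the gene families and windows, the tests of nuclear RNA, of the ribosomal protein genes, of neighbours of another family and of neighbours among genes of 0 to 3 tags, and the bound on shared tags for most lost genes; the other tests were written before their results were seen. The clustered protocadherins, cell adhesion genes of chromosome 5, were higher in the libraries labelled C4-2. All 15 PCDHB genes tested (hg19 140474237 to 140627801) were called higher, with log2 fold changes from 1.13 to 7.36 and a median of 4.21. The 15 PCDHA genes had a median of 4.34, and 22 of 23 PCDHG genes were higher, with a median of 2.53, but the genes of each of these groups share their last exons and so tags, and are not separate signals. On chromosome 15, 24 of 26 small nucleolar RNAs tested of the imprinted SNORD116 cluster (hg19 25296623 to 25351751) were lower (median -1.28, lowest -2.85). Whether these neighbouring copies are separate signals was not tested. Of the HOX clusters, 9 of 10 HOXA genes were lower (median -3.50), 8 of 8 HOXC genes (-1.08), 3 of 6 HOXB genes with 1 higher (-0.76), and 1 of 2 HOXD genes with 1 higher, and a difference between clusters was not tested. Zinc finger genes of chromosome 19 were higher for 143 and lower for 55 of 252, with a median of 0.33. All 1125 genes tested on chromosome 19 were higher for 51.5% and lower for 26.4%, with a median of 0.28. The zinc finger genes thus stood close to their chromosome as a whole, and a difference from it was not tested. These medians are relative to the typical gene. Library totals add 1.004 to the typical gene, more than the size of the HOXB median (-0.76).

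Some genes with high levels in the libraries labelled LNCaP were nearly absent from those labelled C4-2, and the 4 given here were chosen after their values were seen. The thrombospondin gene THBS1 had 181 ± 1.79 CPM against 0.51 ± 0.015, the branched-chain aminotransferase gene BCAT1 99.8 ± 4.44 against 0.26 ± 0.071, the mitochondrial transhydrogenase gene NNT 44.7 ± 2.86 against 0.063 ± 0.019, and the cystatin gene CSTA 76.4 ± 3.64 against 0.31 ± 0.046. By chromosome, genes of 2, 16, 19 and 22 were higher as a group (medians 0.23, 0.37, 0.28 and 0.30) and those of 7, 13 and 15 lower (-0.42, -0.38 and -0.30, each smaller in size than the shift of 1.004 with library totals; camera adjusted p from 0.00048 to 0.038). With an estimated correlation the lowest adjusted p was 0.24. After removal of the GC and length trends 4 chromosomes were called. Across all genes with known GC content, medians ran from -0.24 in the group lowest in GC to 0.30 in the highest. How much of each chromosome's median goes with GC content was not tested. Of windows of 31 neighbouring genes, 14 were higher and 7 lower beyond the bounds of 100 shuffles, including 28 of 31 genes lower at 27825692 to 33072629 on chromosome 13 and 27 higher at 778745 to 2420370 on chromosome 4.

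The stored names pair each sample with the other cell line, and an exchange of labels is a candidate explanation for the low KLK3 of the libraries labelled C4-2. By the prediction set beforehand, exchanged labels would give androgen-induced genes with a median below 0 and KLK3 lower, and right labels a median above 0 and KLK3 higher. The median was 0.19 and KLK3 was lower (-6.46), so neither set was met, with KLK2 and AZGP1 lower but FKBP5 and TMPRSS2 higher. Members that go both ways leave exchanged and right labels such that they cannot be told apart here. A difference between the lines in androgen signalling stays open too, untested.

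Long non-coding RNAs as a class were lower in the libraries labelled C4-2 (58.0% lower and 12.9% higher of 896, median -0.69, smaller in size than the shift of 1.004 with library totals), and ribosomal protein genes had a median of -0.35, which library totals turned to 0.66. The drop was not particular to long non-coding RNAs. Small or structured RNAs were lower for 57.0% and higher for 16.2% of 407 (median -0.76). Remaining classes were lower for 53.5% and higher for 21.4% of 566 (-0.52), and protein-coding genes for 37.5% and 43.5% of 14106 (0.053). Fold changes followed GC content (Spearman's rho 0.18 across genes, which are not independent replicates), with medians from -0.24 in the fifth of genes lowest in GC to 0.30 in the highest. Removing the GC and length trends left the long non-coding median at -0.58 (quartiles -1.32 and 0.040, before -1.41 and -0.019), which argues against those trends as the whole cause, but took the ribosomal protein median to 0.016 (quartiles -0.33 and 0.48, before -0.72 and 0.16) and its adjusted p from 0.049 to 0.86, so the call ended because the median itself moved, and these trends may account for it. GC content was known for 86.3% of the long non-coding genes, and the rest were given the median GC content, so for those the correction for GC is void. More nuclear RNA in the libraries labelled LNCaP, which had the lower exon share, predicted a deeper drop for nuclear RNAs; 15 nuclear and 15 cytoplasmic RNAs differed by -0.35 (one-sided permutation p = 0.13, 100000 resamples), which met neither the bound set for this explanation nor that set against it. The exon share goes with the cell line, so a biological difference between the lines stays open, untested.

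Of 12577 genes with at least 2 CPM in a line, 67 were at least 100-fold lower in the libraries labelled C4-2 and 10 in those labelled LNCaP. Loss of stretches of chromosome predicted lost neighbours beyond chance, a neighbour being the nearest gene with at least 2 CPM that does not overlap the gene (so that NNT and NNT-AS1 are no pair). Of the 77 genes 9 had one, against 0 to 4 in 95% of 1000 random placements, and 4 had one of another gene family (ILDR1 with CSTA and FCHSD1 with ARAP3, upper bound 3.03). The 9 hold both CTAG1A and CTAG1B, which count as a single signal. The 77 also hold SSX2 with SSX2B, CXorf49 with CXorf49B and SOHLH2 with CCDC169-SOHLH2. Both counts thus exceed the number of separate losses, and the placements took no account of copies. PCDHB10 and PCDHB11, also among the 9, were nearly absent from the libraries labelled LNCaP, the parent line, and present in those of its subline. A loss of that stretch before C4-2 arose could not give this under the labels. These genes count for loss only if it came later or the labels are exchanged. CSTA kept 44 and 40 tags in the libraries labelled C4-2, where SLC22A3 kept 1, which argues against loss of CSTA from all cells, and among the 32 genes of 0 to 3 tags only 2, FCHSD1 and ARAP3, had such a neighbour, a number that 60 of 1000 placements reached or passed. The count of 9 met the rule set beforehand, and the limit to 0 to 3 tags was added after it was seen. Loss of stretches and shared regulation of neighbours thus cannot be told apart for these genes, since so few pairs lack tags. Tags shared with copies or overlapping genes were set beforehand to show as a share above 10% and above that of all genes; it was 14.3% (11 of 77) against 13.4%, and an allowance for counting error, added after this was seen, leaves that excess undecided. The exact 95% interval of 7.35% to 24.1% lay below the bound for most of these genes, but that bound was set after the share was seen. The interval also counts pairs of copies or overlapping genes as separate. The other 66 genes neither had counts identical to another gene nor overlapped one on their strand, which argues against shared tags for those 66. Silencing or another biological difference between the lines stays open, untested.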
